A study of Homo sapiens with 10 samples.

How the data were processed

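Total RNA of IMR90 fibroblasts was extracted with Trizol, labelled with biotin and hybridised to Affymetrix HG-U133 Plus 2.0 arrays, per the labels' protocols, with 5 arrays of proliferating and 5 of senescent cells. The deposited values are log2 values, a single one per probe set and array, for 54675 probe sets on 10 arrays. The submitters' processing notes name Partek and GCRMA, a background correction and summarisation method for Affymetrix arrays, without version, role or order. Settings of the background correction and normalisation are not given in the sources used here. The log2 base was read from the range of the deposited values, and the scale is not otherwise stated. The values were not centred per gene or per array, and values below 0 do not occur. Column medians were 3.07, 3.07, 3.07, 3.06 and 3.05 for proliferating 1 to 5 and 3.07, 3.05, 3.08, 3.08 and 3.12 for senescent 1 to 5. Detection calls, scan dates, slides and scanner files were not used here, so neither a probe set's presence nor a scan batch was tested.

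Probe sets were named from the platform's annotation, with symbols updated through gene identifiers in the RefSeq table of assembly GRCh38.p14, which served only for names and for which genes neighbour each other. Of the probe sets, 62 were controls and left out of gene tests, 41091 had 1 gene symbol, 1801 several and 11721 none. Of those with 1 symbol, 41037 were named through their gene identifier and 54 kept the older name. No gene was named from a probe set with several symbols.

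The groups, the main test, the gene lists, the rule for named genes and the alternatives listed below, except where stated, were chosen before the data were examined. A probe set was tested if it lay above its array's 40th percentile on at least 5 of the 10 arrays, which 32790 did, 25930 of them with 1 symbol. Each gene was represented by its tested probe set with the highest mean over all arrays, which gave 12909 genes. Probe sets of a gene could disagree, and 237 called genes had another called probe set of opposite direction. The difference of senescent minus proliferating means was tested two-sided with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. Rose and fell are used for genes past that threshold. A difference of 2-fold is 1 on the log2 scale. For single genes and controls an exact permutation test, two-sided, ran over all 252 assignments of the arrays.

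The 32 gene lists covered the nuclear lamina, nucleoporins, cell cycle, DNA replication and recombination, p53 targets, the senescence secretome, interferon response, lysosome, autophagy, histones and other chromatin proteins, matrix, contractile genes, metabolism, stress, ribosomes, housekeeping genes and markers of epithelial, endothelial, leukocyte and smooth muscle cells. They held 1027 entries, of which 940 were on the array and 858 tested. Lists with at least 5 tested members were tested with limma's camera (preset correlation 0.01) and adjusted over 31 lists. Camera with an estimated correlation, camera on ranks and fry were alternatives. Fry tests whether a list moves on balance in a direction and does not compare it with other genes.

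Named genes were LMNB1 and the senescence criteria, the 12 largest differences in each direction among called genes without overlap between the groups, and up to 4 called members of each list with the largest differences, or the 1 furthest member where none was called. This gave 148 genes, and another 76 were chosen after their values were seen. Signs of RNA quality were read from 3', middle and 5' control probe sets of ACTB and GAPDH, among 19 controls tested.

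Alternatives were no filter, a filter at the 60th percentile, centring on the median of tested genes or of the housekeeping list, quantile normalisation, a replicate block, eBayes with trend and robust, array weights, the mean of a gene's probe sets, exclusion of probe sets named as shared, and leaving out each array in turn. A covariate of the ACTB control and a comparison of 4 against 4 arrays, without proliferating 2 and senescent 5 at the low end of the second principal component, were chosen after seeing the data. Neighbouring protein-coding genes were compared with 10000 random orders, also without pairs whose symbols share their first letters, where all replication-dependent and linker histone genes counted as a single family, and families of genes with a shared symbol root by a hypergeometric test adjusted over 218 families and both directions. Figures used Python 3.11.15 with matplotlib 3.10.9, numpy 2.4.6 and pandas 2.3.3, and tables used version 1.17.8 of data.table.

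The gene and list tests were tested on simulated data shaped like the comparison of 5 against 5 arrays over 12909 genes. With 50 genes changed at each size, 60% were called at a log2 difference of 0.5, 98% at 1 and 100% at 2 and 4. Of 187 calls 8 were false. The shifted list was found, and 0 lists sharing no member with it passed. The simulated genes varied independently of each other, and 200 of them were changed for the gene test. The list result therefore does not cover correlated genes, and regrouped real arrays, described below, passed many lists where no gene was called. In the real comparison 61.3% of tested genes passed, which makes the adjusted threshold less strict than in the simulation. The simulated shares of called genes therefore do not describe the real comparison.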

Results

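Genome-wide expression was measured in IMR90 cells, a normal human fibroblast line derived from fetal lung, in 2 states. Proliferating cells at 28 population doublings were hybridised to 5 arrays, and senescent cells at 90 population doublings were hybridised to another 5. The senescent cells had been passaged until they stopped growing and were then held for 2 weeks, and all cells were grown in 3% oxygen and 10% serum. The comparison asks how expression differs between the proliferating state and the senescent state, in which the series title places a loss of lamin B1. None of the labels names an experimental knockdown, so the arrays compare cell states, and passage number differs together with growth state. Array medians lay between 3.05 and 3.12 on the deposited log2 scale, and the number of arrays, 5 per group, limits the precision. The labels do not say whether the arrays of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

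LMNB1, which encodes the B-type nuclear lamin B1, was measured by 1 probe set and was lower on every senescent array than on every proliferating array. Its log2 value was 10.93 ± 0.09 (SD, n = 5) in proliferating cells and 5.42 ± 0.36 (SD, n = 5) in senescent cells. LMNB1 thus fell by 5.51 on the log2 scale (SE 0.15), which is 45.6-fold lower, with limma's adjusted p = 6.7e-10 and an exact permutation p = 0.00794, the smallest that 252 assignments of the arrays allow.

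The labels name p16 induction and lower cyclin expression among the criteria by which senescence was judged in these cells, so the following genes are not independent evidence of it. CDKN2A, the gene of the CDK inhibitor p16, rose from 4.43 ± 0.96 to 7.63 ± 0.18 (SD, n = 5 each), a log2 difference of 3.20 (SE 0.39, limma's adjusted p = 4.3e-05), which was 2.11 with a covariate for RNA integrity described below (adjusted p = 0.0019). The mitotic cyclins CCNA2, CCNB1, CCNB2 and CCNF fell by 2.85, 3.65, 4.82 and 3.47, and the G1/S cyclin CCNE2 fell by 3.45 (log2, limma). All 3 D-type cyclins, which pair with CDK4 and CDK6, went the opposite way. CCND2 rose 117-fold, from 7.32 ± 0.30 to 14.19 ± 0.05 (SD, n = 5 each), and CCND1 and CCND3 rose 2.35-fold and 2.31-fold. The other E-type cyclin, CCNE1, differed by -0.32 (SE 0.17), which did not pass the threshold (limma's adjusted p = 0.13), although it did with arrays centred on housekeeping genes (adjusted p = 0.020; up to 0.27 under other alternatives). Of the 10 genes, 6 moved in the direction the labels state, and the 10 tested genes gave an exact permutation p of 0.00794 each except CCNE1 with 0.143.

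**Figure D1:**
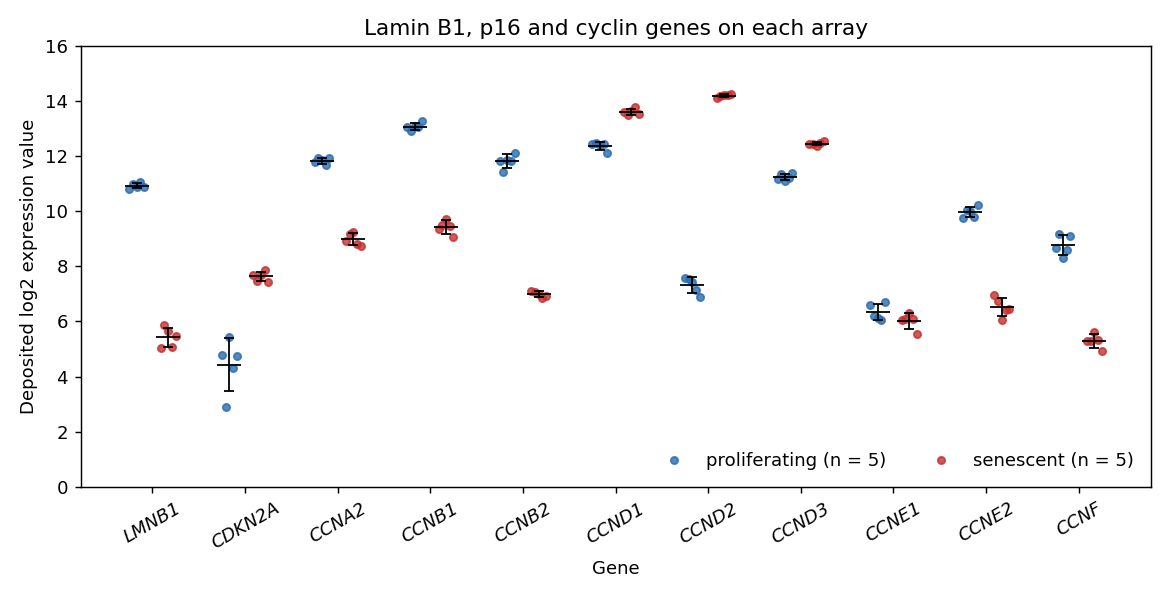
Deposited log2 expression values (vertical axis) of LMNB1, CDKN2A and 9 cyclin genes (horizontal axis) on each of the 5 proliferating (blue) and 5 senescent (red) arrays. Points are arrays, black dashes are group means and bars are ± 1 SD; LMNB1 lies at 10.93 and 5.42 in the respective groups, CCND2 at 7.32 and 14.19, and the groups overlap for CCNE1.

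Expression differed widely between the states. Of 12909 genes tested, 7913 (61.3%) passed limma's adjusted threshold, 4004 higher and 3909 lower in senescent cells. At least 2-fold differences were seen for 1294 higher and 1323 lower genes, and at least 4-fold differences for 380 and 548. The 5 senescent values all lay on the same side of the 5 proliferating values for 51.8% of tested genes, where chance gives 0.794%. Correlations over tested genes, which are not independent replicates, were 0.993 to 0.998 between arrays of a group and 0.930 to 0.939 between arrays of different groups. The median difference over tested genes was 0.04. Centring arrays on housekeeping genes moved that median by -0.139 and changed the split of all calls from 50.6% higher to 38.3% higher, so small differences carry a direction only relative to the scaling. This centring subtracts each array's median over the housekeeping list, and the median difference of the list's own members went from -0.07 to -0.21. It is thus another scaling and does not hold the housekeeping genes unchanged.

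The largest increases included genes with little signal in proliferating cells. TMEM178B rose 165-fold, the axon guidance receptor gene SEMA6A 154-fold and the long noncoding RNA PURPL, known as a p53-regulated transcript, 118-fold (2.56 ± 0.03 to 9.45 ± 0.15, SD, n = 5 each). The cartilage link protein gene HAPLN1, ELMOD1, the aggrecan-cleaving protease gene ADAMTS5, the integrin gene ITGA8 and the chemokine receptor gene ACKR3 rose by log2 differences of 6.26, 6.15, 6.15, 6.13 and 6.05. TNFSF15, the histone gene H2BC4 and LIMCH1 followed with 5.95, 5.86 and 5.84. Limma's adjusted p was at most 2.2e-07 for each of these genes.

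The 12 largest decreases were of the same size. HHIP, whose product binds hedgehog ligands, fell from 10.00 ± 0.65 to 2.66 ± 0.36 (SD, n = 5 each), which is 162-fold lower, and the retinaldehyde dehydrogenase gene ALDH1A3 fell by 7.01 on the log2 scale. The transcription factor gene SOX11, the MYC- and E2F-regulated gene CDCA7 and the potassium channel gene KCNK2 fell by 6.66, 6.48 and 6.31. Histone genes H3C2, H2BC14, H4C13 and H3C11 fell by 7.06, 6.91, 6.56 and 6.16, and the mitotic genes KIF20A, NEK2 and NUF2 fell by 6.38, 6.34 and 6.28 (limma's adjusted p at most 4.2e-07 for each). CDCA7 fell by 1.65 without shared probe sets (adjusted p = 0.0034) and by 4.06 with the mean of its probe sets, and SEMA6A and ELMOD1 rose by 4.02 and 3.10 with that mean. Many of these folds set a clear signal against background: on all arrays of the lower group SEMA6A, PURPL, HAPLN1, ELMOD1, ACKR3, TNFSF15, H2BC4, LIMCH1, HHIP, ALDH1A3, CDCA7, H3C2, H2BC14, H4C13 and H3C11 lay below the array's 60th percentile (4.64 to 4.77). The size of such a fold depends on the background correction, and list members of which the same is true are given below as having low signal in that group.

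Gene groups were taken from 32 lists fixed before the data were examined. Members that moved against their list, and others given in counts of 5 or fewer, were chosen by name after their values were seen. Of 31 lists large enough to test, 23 passed camera's adjusted threshold, 14 lower and 9 higher, and 11 did so with an estimated correlation: lamina, cyclins, mitosis, replication, recombination, p53 targets, lysosome, histone variants, chromatin methylation, high-mobility-group and NRF2 genes. Signal at the 3' end of transcripts relative to the 5' end, a sign of RNA integrity, also differed between the groups for ACTB. The ACTB control difference was 2.07 ± 0.14 in proliferating and 2.32 ± 0.10 in senescent samples (SD, n = 5 each, exact permutation p = 0.00794, not adjusted over the 19 controls). For GAPDH the 3' minus 5' difference was higher in senescent samples by 0.15, with an exact permutation p = 0.135. The 3' minus middle differences were higher by 0.18 for ACTB and 0.23 for GAPDH (exact permutation p = 0.00794 each). The ACTB 3' minus 5' difference of 0.25 lies between the same groups of samples that every list below compares. Counts with it as a covariate, an alternative chosen after seeing the data, are therefore given beside each group.

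**Figure D2:**
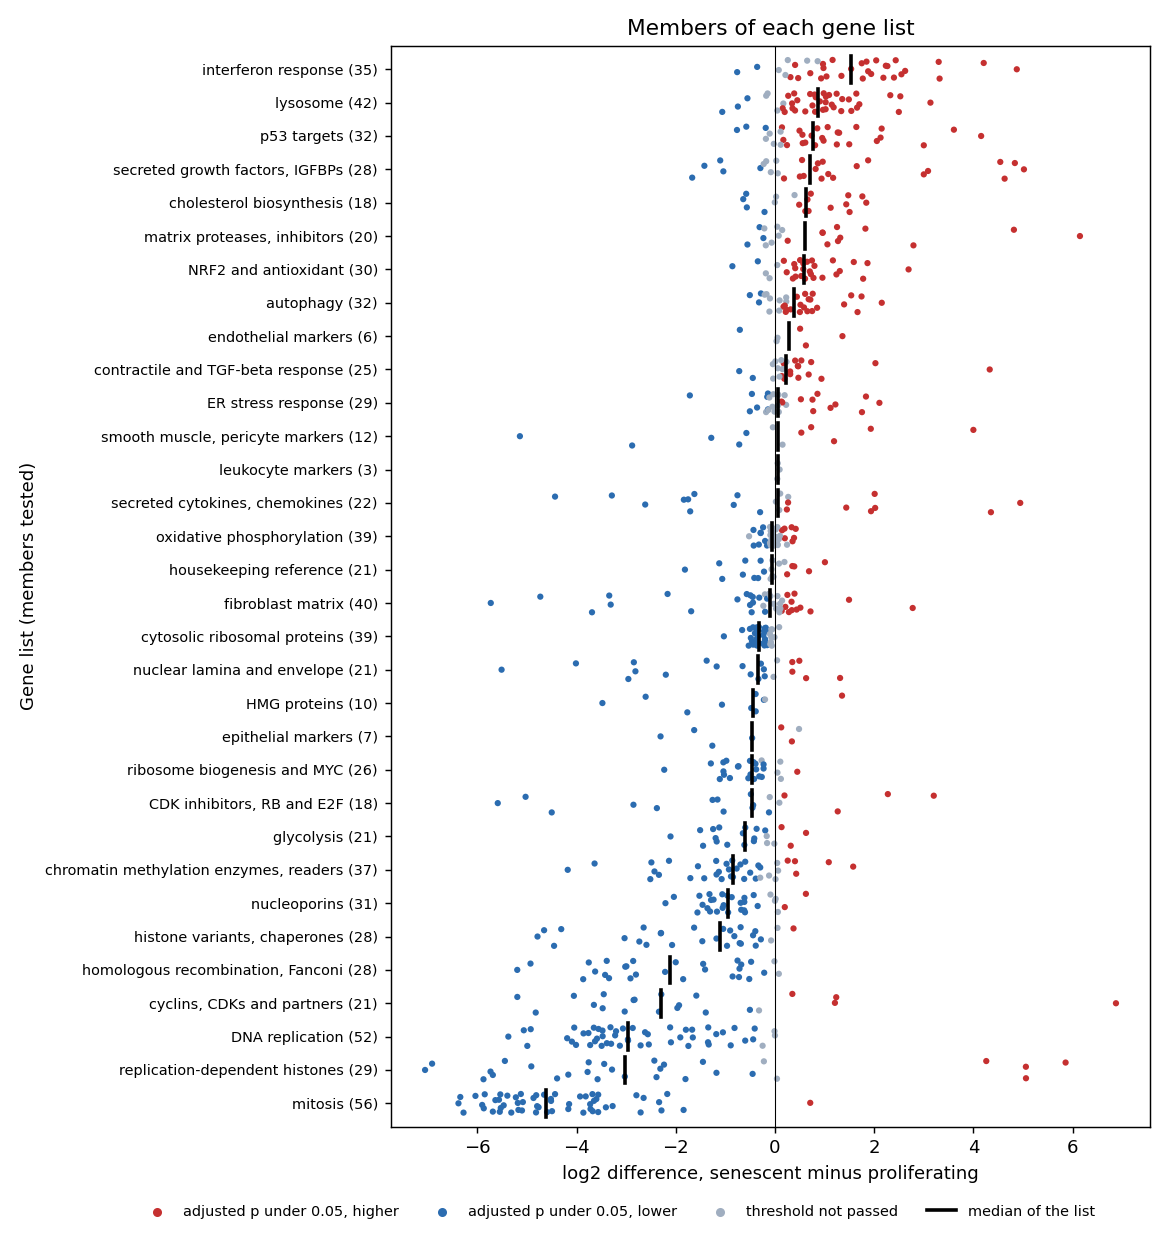
Log2 difference between senescent and proliferating cells (horizontal axis, senescent minus proliferating) for each tested member of the 32 gene lists (vertical axis, with the number of members tested). Red and blue points passed the adjusted threshold, grey points did not, and black bars are list medians, which run from -4.62 for mitosis to 1.54 for the interferon response.

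Genes of cell division showed the largest shift. Of 56 mitosis genes 55 fell and 1 rose (the same adjusted over the list alone), with a median of -4.62 and examples KIF20A, NEK2, NUF2 and the kinetochore gene SPC25 (-6.04). The exception was SPC24 (0.71), whose probe sets disagreed, another of them differing by -5.05, and the mean of both fell by 2.17. Among 52 DNA replication genes 49 fell and none rose (the same adjusted over the list alone, median -2.96). The largest falls were those of the checkpoint adaptor gene CLSPN (-5.38), the helicase subunit gene CDC45 (-5.06), the thymidine kinase gene TK1 (-4.99) and POLE2 (-4.92). Homologous recombination and Fanconi genes fell in 26 of 28 cases with none higher (the same adjusted over the list alone; median -2.11), including BLM (-5.20), EXO1 (-4.93), RAD51AP1 (-3.87) and RAD54L (-3.75). CLSPN, CDC45, TK1, POLE2, BLM, EXO1 and RAD54L had low signal in senescent cells. Camera's adjusted p was 5.4e-29, 8.2e-22 and 4.5e-11 for these 3 lists, and 0.024, 0.022 and 0.022 with an estimated correlation. With the ACTB covariate 55, 51 and 25 members fell.

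Regulators of the cycle moved in both directions. Among 21 cyclins, CDKs and partners 16 fell and 4 rose (the same adjusted over the list alone; median -2.29, camera's adjusted p = 9.1e-06), and members include the criteria genes given above. CDC25C and CDK1, the phosphatase and kinase that start mitosis, fell by 5.19 and 4.05. The 3 D-type cyclins rose, and of their partner kinases CDK6 rose (0.35) and CDK4, named after its value was seen, fell (-1.40). Among 18 CDK inhibitor, RB and E2F genes 12 fell and 4 rose (the same adjusted over the list alone; median -0.47). CDKN3, E2F8 and E2F2 fell by 5.59, 5.03 and 4.50, and the inhibitor genes CDKN2A, CDKN2B (p15) and CDKN1A (p21) rose by 3.20, 2.28 and 1.27 together with E2F7 (0.19), whereas the inhibitor genes CDKN1B (p27) and CDKN1C (p57), also named afterwards, fell by 1.16 and 1.26. CDC25C, E2F8 and E2F2 had low signal in senescent cells. Camera's adjusted p for this list was 0.0076, and the call was lost with an adjusted p = 0.054 with an estimated correlation. Fitted together with the ACTB control, 15 and 11 members of these lists fell and 4 and 3 rose.

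Genes of the nuclear lamina and envelope moved in both directions. Of 21 members 14 fell and 5 rose (the same adjusted over the list alone; median -0.33, camera's adjusted p = 0.0081). Besides LMNB1, the lamina-associated polypeptide gene TMPO fell by 4.01, nurim (NRM, low signal in senescent cells) by 2.96 and the nesprin gene SYNE2 by 2.85, and the B-type lamin gene LMNB2 and the lamin B receptor gene LBR fell by 2.81 and 2.20. The nesprin gene SYNE1, the prelamin A protease gene ZMPSTE24, TOR1AIP1, TOR1A and LEMD3 rose by 1.31, 0.63, 0.49, 0.35 and 0.35. Among 31 nucleoporins 25 fell and 2 rose (the same adjusted over the list alone; median -0.94), with NDC1, NUP155, NUP85 and NUP62 lower by log2 differences of -2.21, -2.04, -1.56 and -1.52 and POM121 (0.62) and NUP42 (0.20) higher. Camera's adjusted p was 1.0e-07 for nucleoporins, with an adjusted p = 0.054 with an estimated correlation. Fitted together with the ACTB control, 12 and 24 members of these lists fell and 4 and 1 rose.

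Replication-dependent histone genes, transcribed in S phase to package new DNA, fell in 23 of 29 cases, by a list median of -3.03, and 4 rose (the same adjusted over the list alone). H3C2, H2BC14 and the linker histone gene H1-1 fell by 7.06, 6.91 and 5.88. H2BC4 rose from 3.00 ± 0.34 to 8.86 ± 0.18 (SD, n = 5 each), and H2AC6, H2BC21 and H2BC12 rose by 5.06, 5.06 and 4.26. H2AC6 and H2BC21 were measured only by probe sets whose names mark them as shared between similar transcripts. Among the genes counted as fallen, H4C8, H2AC25 and H2BC5 had probe sets that moved in opposite directions. H4C8 was at -1.80 on a shared and at 6.52 on a specific probe set, H2AC25 at -1.45 and 1.16, and H2BC5 at -2.31 and 2.82 on its 2 shared probe sets, and these genes were named after their values were seen. Camera's adjusted p was 7.6e-07, and the adjusted p = 0.11 with an estimated correlation. With the ACTB covariate 22 fell and 4 rose, the median was -2.42 instead of -3.03, and 26 of the 29 differences were smaller in size.

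**Figure D3:**
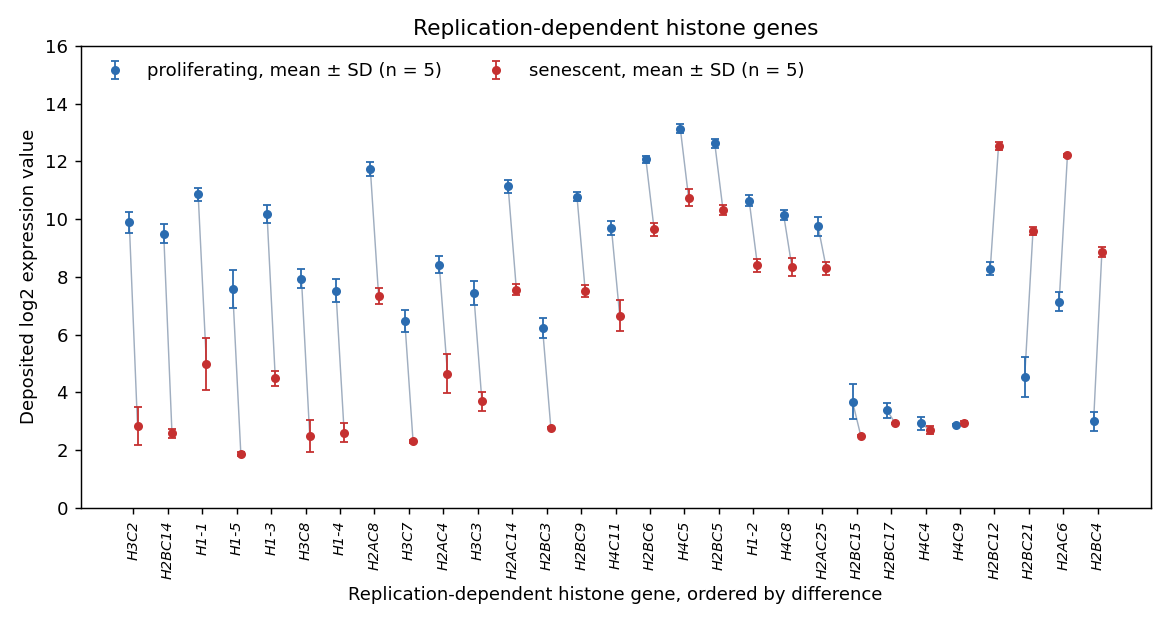
Deposited log2 expression (vertical axis) of 29 replication-dependent histone genes (horizontal axis, ordered by difference) in proliferating (blue) and senescent (red) cells. Points are means of 5 arrays, bars are ± 1 SD and grey lines join the groups; H2BC12, H2BC21, H2AC6 and H2BC4 at the right end are higher in senescent cells, while H3C2 at the left end fell by 7.06.

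Other chromatin genes were mostly lower. Of 28 histone variants and chaperones 25 fell and 1, the chromatin remodeller gene ATRX (0.37), rose (the same adjusted over the list alone; median -1.11, camera's adjusted p = 2.2e-10), with the assembly factor gene CHAF1B (-4.79), the centromeric histone gene CENPA (-4.65), its chaperone gene HJURP (-4.45) and ASF1B (-4.31) leading. Among 37 chromatin methylation enzymes and readers 27 fell (28 adjusted over the list alone) and 5 rose (median -0.85, camera's adjusted p = 9.1e-06). EZH2, the H3K27 methyltransferase gene, fell by 4.18, UHRF1 by 3.64, CBX2 by 2.51 and the H3K9 methyltransferase gene SUV39H1 by 2.49. The polycomb reader gene CBX7 (1.58) and the EZH2 paralogue EZH1 (1.09) rose, as did KDM5B (0.43), KDM6B (0.40) and KMT2D (0.26), and 3 rose with housekeeping centring. CHAF1B, CENPA, ASF1B and CBX2 had low signal in senescent cells, and CBX7 had it in both groups. High-mobility-group genes fell in 8 of 10 cases (9 adjusted over the list alone; median -0.43, camera's adjusted p = 0.00070), with HMGB2 at -3.48, HMGB3 at -2.61 and HMGN2 at -1.77. HMGN5 rose by 1.35 on a shared probe set, and its remaining probe set differed by 0.12 and did not pass. Given the ACTB covariate, 24, 24 and 8 members of these 3 lists fell.

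Targets of p53 rose in 24 of 32 cases (median 0.77, camera's adjusted p = 1.5e-05; 24 higher and 4 lower adjusted over the list alone). The decoy receptor gene TNFRSF10C rose by 4.16, the mitophagy gene SPATA18 by 3.61, the secreted stress factor gene GDF15 by 3.00 and the ribonucleotide reductase gene RRM2B by 2.15. The 3 members that fell were the kinase gene PLK2 (-0.77), the pro-apoptotic gene BAX (-0.58) and AEN (-0.19). TNFRSF10C and GDF15 had low signal in proliferating cells. With housekeeping centring 20 rose and 5 fell. Given the ACTB covariate, 20 rose.

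Secreted factors did not move as a single group. Among 22 cytokines and chemokines of the senescence secretome 8 rose and 10 fell (the same adjusted over the list alone; camera's adjusted p = 0.90), and the median of 0.05 and mean of -0.07 differ in sign, with the median at -0.09 after housekeeping centring. BMP2 rose 30.8-fold, and the interferon-inducible chemokine gene CXCL10 rose from 2.69 ± 0.06 to 7.05 ± 0.35 (SD, n = 5 each), whereas the chemokine gene CXCL12 fell by 4.43 and IL1B by 3.29. Senescence-associated genes chosen after their values were seen also diverged, with CXCL8 at 1.94, CCL2 at -2.62, IL6 at -1.84 and IL1A at -0.83, the last of which did not pass with the ACTB covariate (adjusted p = 0.16). IL1B, IL6 and CXCL12 had array proliferating 5 apart from the other proliferating arrays. Of 28 growth factors and IGF-binding proteins 18 rose and 5 fell (the same adjusted over the list alone; median 0.70, camera's adjusted p = 0.0018, adjusted p = 0.054 with an estimated correlation). ANGPTL4, the angiopoietin gene ANGPT1, the neuregulin gene NRG1 and WNT16 rose by 5.02, 4.84, 4.63 and 4.54, and VEGFA, WNT2, KITLG, PDGFA and IGFBP3 fell by 1.67, 1.42, 1.10, 1.04 and 0.29. Among 20 matrix proteases and inhibitors 11 rose and 3 fell (the same adjusted over the list alone; median 0.61, camera's adjusted p = 0.0076, adjusted p = 0.11 with an estimated correlation). ADAMTS5, stromelysin (MMP3), SERPINE2 and ADAMTS1 rose by 6.15, 4.82, 2.79 and 1.82, and CTSK (-0.55), MMP1 (-0.31) and PLAUR (-0.23) fell. CXCL10, ANGPTL4 and MMP3 had low signal in proliferating cells and IL1B, IL1A and WNT2 in senescent cells, so the sizes of their differences depend on the background correction. The protease median was 0.11 without the filter on low values. With the ACTB covariate 7 cytokines rose and 8 fell, with a median of -0.07, 16 growth factors rose and 4 fell, and 9 proteases rose and 3 fell.

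Interferon-response genes rose in 28 of 35 cases and 2 fell (the same adjusted over the list alone), with a median of 1.54, the highest of the lists. IFI6 rose 29.4-fold, SAMD9L 18.5-fold, the transcription factor gene IRF1 9.99-fold and HERC6 9.86-fold, and OAS3 (-0.76) and the immunoproteasome gene PSMB8 (-0.36) fell. Camera's adjusted p was 1.1e-07, and the adjusted p = 0.090 with an estimated correlation. Fitted together with the ACTB control, 24 rose and 1 fell, the median was 1.33, and 27 of the 35 differences were smaller in size.

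Lysosomal genes rose in 35 of 42 cases and 3 fell (the same adjusted over the list alone; median 0.86, camera's adjusted p = 1.0e-07). The cathepsin gene CTSO rose by 3.14, the lysosomal hydrolase genes SGSH and FUCA1 by 2.53 and 2.50, and the cholesterol transporter gene NPC1 by 2.33, while GUSB (-1.06), PPT1 (-0.75) and CTSK (-0.55) fell. Of 32 autophagy genes 21 rose and 3 fell (the same adjusted over the list alone; median 0.38, camera's adjusted p = 0.00076, adjusted p = 0.054 with an estimated correlation). GABARAPL1, WIPI1, MAP1LC3B and the cargo receptor gene SQSTM1 rose by 2.15, 1.75, 1.67 and 1.54, and ATG5 (-0.51), PIK3R4 (-0.32) and ULK2 (-0.28) fell. The fall of ULK2 came from 1 shared probe set: its value was -0.0037 without shared probe sets (adjusted p = 0.97) and -0.04 with the mean of its 4 probe sets (0.46), where PIK3R4 was at -0.14 (0.090). With housekeeping centring 16 autophagy genes rose and 6 fell, with a median of 0.24. NRF2 and antioxidant genes rose in 25 of 30 cases and 2 fell (the same adjusted over the list alone; median 0.59, camera's adjusted p = 2.0e-05). Glutathione peroxidase GPX3 rose by 2.69 and the aldo-keto reductase genes AKR1C1, AKR1B10 and AKR1C2 by 1.87, 1.78 and 1.59, while GPX4 (-0.86) and the transketolase gene TKT (-0.35) fell. FUCA1 and AKR1B10 had low signal in proliferating cells. Fitted together with the ACTB control, 31, 16 and 22 members of these lists rose, and AKR1B10 lost its call (adjusted p = 0.084).

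Metabolic groups differed from each other. Glycolysis genes fell in 15 of 21 cases (16 adjusted over the list alone; median -0.60, camera's adjusted p = 0.00024, adjusted p = 0.091 with an estimated correlation). ALDOC, ENO1, the mitochondrial kinase gene PDK1 and TPI1 fell by 2.11, 1.51, 1.45 and 1.25, and HK2 (0.63), PFKM (0.32) and PFKFB3 (0.13) rose. Of 39 oxidative phosphorylation genes 7 rose, 8 fell and 24 did not pass (6 and 8 adjusted over the list alone; median -0.05, camera's adjusted p = 0.52), a balance that became 9 rising and 6 falling with median centring and 2 and 19 with housekeeping centring. ENO1 and TPI1 differed by only -0.36 and -0.41 on specific probe sets, whose signal was lower, and did not pass on them (adjusted p = 0.057 and 0.15). NDUFA9 (-0.43) and NDUFB5 (0.42) had differences under 2-fold, as did NDUFV1 (-0.43) and NDUFA2 (0.38). ALDOC had low signal in senescent cells. Cholesterol biosynthesis genes rose in 11 of 18 cases and 4 fell (the same adjusted over the list alone; median 0.63, camera's adjusted p = 0.022, adjusted p = 0.19 with an estimated correlation). SC5D, MSMO1, DHCR7 and HMGCS1 rose by 1.84, 1.76, 1.51 and 1.48, and SCD (-0.64), EBP (-0.58), INSIG1 (-0.57) and ACAT2 (-0.21) fell. Without the filter on low values this list did not pass (adjusted p = 0.052). With the ACTB covariate 14 glycolysis genes fell, 10 cholesterol genes rose and 5 oxidative phosphorylation genes rose and 6 fell, NDUFV1 being at -0.19 and no longer called (adjusted p = 0.48).

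Most translation genes were lower. Of 39 cytosolic ribosomal protein genes 30 fell and none rose (32 adjusted over the list alone; median -0.32, camera's adjusted p = 1.7e-06, adjusted p = 0.17 with an estimated correlation), with RPS9, RPL8, RPL18 and RPL12 at -1.03, -0.66, -0.53 and -0.50. Ribosome biogenesis and MYC genes fell in 21 of 26 cases and 1, RRP12 (0.45), rose (the same adjusted over the list alone; median -0.46, camera's adjusted p = 7.2e-05, adjusted p = 0.13 with an estimated correlation). The nucleolar methyltransferase gene FBL, UTP20, MYC and NOLC1 fell by 2.23, 1.29, 1.11 and 1.04. Given the ACTB covariate, 20 ribosomal protein genes and 14 biogenesis genes fell, against 30 and 21 without it, and the medians were -0.19 and -0.45. RPS9 and RPL8 were then at -0.63 and -0.35.

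Of 40 fibroblast matrix genes 12 rose and 17 fell (13 and 18 adjusted over the list alone; median -0.10, camera's adjusted p = 0.19). With housekeeping centring 6 rose and 22 fell, with a median of -0.24, and without the filter the list passed as lower (adjusted p = 0.015). The proteoglycan gene BGN, COL15A1, the hyaluronan synthase gene HAS2 and THBS2 fell by 5.73, 4.73, 3.69 and 3.34. Contractile and TGF-beta response genes rose in 15 of 25 cases and 2, MYH11 (-0.72) and CNN2 (-0.45), fell (the same adjusted over the list alone; median 0.23, camera's adjusted p = 0.0071, adjusted p = 0.11 with an estimated correlation). The YAP-responsive gene ANKRD1 rose by 4.33, SMAD7 by 2.03, ID2 by 0.94 and LMOD1 by 0.73. With housekeeping centring 10 rose and 3 fell, with a median of 0.09. The other 3 tested probe sets of MYH11 were higher, by 0.27, 0.71 and 0.55, and its mean over probe sets was 0.20. BGN had low signal in senescent cells and ANKRD1 in proliferating cells. Endoplasmic reticulum stress genes rose in 11 of 29 cases and fell in 7 (the same adjusted over the list alone; median 0.07, camera's adjusted p = 0.37), a balance that became 9 and 9 with housekeeping centring and 11 and 4 with median centring. ATF3, the stress sensor gene ERN1 and DNAJB9 rose by 2.11, 1.84 and 1.75, while the asparagine synthetase gene ASNS fell by 1.72. Given the ACTB covariate, 9 matrix genes rose and 14 fell, 10 stress genes rose and 5 fell, and 14 contractile genes rose, while MYH11, CNN2 and LMOD1 lost their calls (adjusted p = 0.36, 0.49 and 0.23).

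Reference genes were not stable: of 21 housekeeping genes 5 rose and 9 fell (the same adjusted over the list alone; median -0.07, camera's adjusted p = 0.26, with 4 rising, 13 falling and a median of -0.21 after housekeeping centring). HPRT1, GPI and GUSB fell by 1.82, 1.12 and 1.06, while EMC7 (1.01), REEP5 (0.69), B2M (0.39), RAB7A (0.35) and CHMP2A (0.25) rose. Camera called no list of markers of other cell types, while fry, which does not compare a list with other genes, called the endothelial (adjusted p = 3.1e-05) and epithelial (9.4e-05) lists. Fry also called the housekeeping (adjusted p = 2.3e-05), endoplasmic reticulum stress (5.6e-05) and fibroblast matrix (0.0071) lists, which camera did not. Leukocyte markers had 3 tested members, too few for a list test, and 0 passed limma's threshold, also before adjustment. The furthest from 0 among them was the lysozyme gene LYZ at 0.09 (limma's adjusted p = 0.097, exact permutation p = 0.032), which became -0.05 with housekeeping centring (adjusted p = 0.59). LYZ passed with eBayes set to trend and robust (adjusted p = 0.044) and, at 0.12, without senescent 2 (0.049). Tested epithelial markers numbered 7, with EPCAM, KRT7, KRT19 and KRT18 lower by log2 differences of -2.31, -1.63, -1.26 and -0.46 and SFTPC (0.34) and SFTPB (0.13) higher (3 higher and 4 lower adjusted over the list alone; median -0.46, camera's adjusted p = 0.38). Tested endothelial markers numbered 6, with ENG (1.36), TEK (0.62) and FLT1 (0.51) higher and ROBO4 (-0.71) lower (the same adjusted over the list alone; median 0.28, camera's adjusted p = 0.26). ERG and EMCN were not called and had low signal in both groups. Other markers did not pass the filter on low values and were not tested. Among these were endothelial PECAM1, CDH5, VWF and KDR, epithelial CDH1, KRT5, KRT8 and NKX2-1, and leukocyte CD14, CD3E and ITGAM. TEK had another probe set that differed by -1.08. Among 12 smooth muscle and pericyte markers 5 rose and 5 fell (the same adjusted over the list alone; median 0.06, camera's adjusted p = 0.98; camera's direction was higher and the mean was -0.18). SYNPO2, RGS5, MCAM, LMOD1 and ACTG2 rose by 4.00, 1.93, 1.19, 0.73 and 0.53, and KCNJ8, ABCC9, NOTCH3, MYH11 and CSPG4 fell by 5.14, 2.88, 1.28, 0.72 and 0.58. No epithelial marker rose with housekeeping centring, where 4 still fell, and SFTPB became -0.01. The smooth muscle median turned to -0.08 and the endothelial median was 0.14 under the same centring. KRT7, ROBO4, KCNJ8 and ABCC9 had low signal in senescent cells, RGS5 in proliferating cells and LYZ in both. With the ACTB covariate 0 leukocyte markers passed, 5 housekeeping genes rose and 9 fell, 1 epithelial marker rose and 3 fell, 2 endothelial markers rose and 1 fell, and 4 smooth muscle markers rose and 4 fell, with KRT7 and FLT1 no longer called (adjusted p = 0.14 and 0.22).

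Some of the members named after their values were seen had calls near the threshold. On leaving out 1 array, 11 of these 76 genes lost their call, and for each of them between 4 and 8 of the 10 arrays had this effect. Each of them also lost its call under other alternatives. The largest adjusted p (limma) was 0.113 for PIK3R4 without senescent 4 and 0.112 for NUP42 without proliferating 4. It was 0.0961 for AEN without senescent 5 and 0.0905 for CTSK without proliferating 1. PSMB8 reached 0.0825 without senescent 2, SFTPB 0.0708 and ACAT2 0.0635 without senescent 3, MMP1 0.0687 without proliferating 5, E2F7 0.0622 and PFKFB3 0.0587 without senescent 4, and ULK2 0.0614 without senescent 5. Without shared probe sets KDM5B and KMT2D differed by 0.44 and 0.22, against 0.43 and 0.26 with them, and no longer passed (adjusted p = 0.0857 and 0.124). B2M and RRP12 fell short with smaller differences, 0.11 and 0.12 against 0.39 and 0.45 (adjusted p = 0.492 and 0.149). With housekeeping centring, which lowers every difference by the same amount, CHMP2A, KDM6B, SFTPC and again KMT2D were at 0.11, 0.26, 0.20 and 0.12 and did not pass (0.229, 0.169, 0.165 and 0.223), nor did E2F7 at 0.05, NUP42 at 0.06 and PFKFB3 at -0.0060 (0.527, 0.537 and 0.943). BAX was at -0.32 with the mean of its probe sets and did not pass (0.0541). LEMD3, WNT2 and again KDM6B were at 0.23, -1.15 and 0.48 with the ACTB covariate, against 0.35, -1.42 and 0.40 without it, and did not pass (0.0518, 0.103 and 0.0941).

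Further genes kept their calls while the size of the difference depended on the probe sets or the covariate. With the mean of their probe sets CCNB2 and CLSPN fell by 2.55 and 3.13, TNFRSF10C, ANGPT1 and IRF1 rose by 2.01, 3.08 and 2.11, and NPC1, SQSTM1, ERN1 and SYNE1 rose by 1.31, 0.79, 0.85 and 0.63. HPRT1, ABCC9 and RPL18 fell by 0.88, 1.00 and 0.31 in that setting, and NOLC1 (-1.66), REEP5 (1.06) and PLAUR (-0.35) differed by more than on a single probe set. RGS5 and CSPG4 were at 1.01 and -1.10 without shared probe sets. With the ACTB covariate TOR1AIP1 (0.33), HMGN5 (0.83) and BAX (-0.33) came closer to 0, while OAS3 (-1.21), CTSK (-1.08), MMP1 (-0.50) and ULK2 (-0.48) moved away from it.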

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

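The check for a value far from the other 4 of its group was fixed beforehand, and it was also applied to the 76 genes chosen after their values were seen. It covered 518 groups of 5 values and picked out 52, where chance gives about 1 in 20, or 25.9. Of these, 20 lay on proliferating 5 and 11 on senescent 5, so the values are not spread evenly over the arrays.

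On proliferating 5, IL1B (4.381) and IL6 (5.579) lay below the other proliferating arrays, where IL1B was at least 6.746 and IL6 at least 7.103, while CXCL12 (10.09) lay above. The hedgehog-binding gene HHIP (8.842), the matrix genes COL15A1 (9.172) and THBS2 (10.33), CCND1 (12.1), CDKN1C (5.162), GABARAPL1 (9.132), LMOD1 (4.222), ASNS (10.59), TEK (9.59), KDM6B (6.629) and SCD (12.44) were lower there, and ID2 (10.54) was higher. Mean values of the cyclin list (10.55), the mitosis list (10.91) and the epithelial markers (6.559) were higher on this array, and those of the secretome cytokines (6.347) and fibroblast matrix genes (11.11) were lower.

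On senescent 5, SGSH (11.02), ANKRD1 (8.171) and the mean of the contractile list (10.98) lay above the other senescent arrays. COL15A1 (4.993), GPX3 (8.348), NDUFV1 (8.622), PDK1 (10.6), MYC (9.471), LEMD3 (10.03), REEP5 (12.15) and the mean of the matrix list (10.68) lay below. On senescent 3, FLT1 (9.227), ACTG2 (13.42), ULK2 (8.744), the interferon list mean (8.281) and the GAPDH 3' minus 5' control (0.2841) were higher than on the other senescent arrays, and NUP155 (7.905) and SPC24 (9.595) were lower. On proliferating 2, NDUFV1 (9.886), ENO1 (12.54), FBL (13.05), BAX (9.357) and CNN2 (11.89) were higher and the GAPDH 3' minus middle control (1.009) was lower.

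Single values apart from their group were also H3C2 (4.01) and E2F2 (2.237), both higher on senescent 2, and BLM (4.128), higher on senescent 1. H1-1 (3.4) and PIK3R4 (7.54) were lower on senescent 4. ULK2 (9.106) and the mean of the CDK inhibitor, RB and E2F list (8.892) were higher on proliferating 3, and SYNPO2 (6.036) was lower on proliferating 1.

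Probe sets without a single gene symbol, which no comparison of genes used, also differed. Of 6802 tested with limma, 385 were at least 2-fold higher and 399 at least 2-fold lower in senescent cells.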

How the results depend on the processing

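The ACTB covariate and the comparison of 4 against 4 arrays were chosen after the result was seen. LMNB1 kept its direction and its side of the threshold under all alternatives run. The counts of genes in each direction and of senescence criteria stayed within 1.5-fold of their main values. Within that limit the balance of directions moved: 38.3% of calls were higher with housekeeping centring and 55.5% with median centring, against 50.6% in the main run. Leaving out 1 array gave 3781 to 4024 higher and 3742 to 3946 lower genes, 1263 to 1314 and 1295 to 1347 by at least 2-fold, LMNB1 from -5.62 to -5.42, 6 criteria, 146 named genes past the threshold, 23 lists and an ACTB control difference from 0.196 to 0.281. With the covariate the genes higher in senescent cells numbered 3034 and the genes lower in senescent cells 3342, LMNB1 was -5.45 and 141 named genes passed. Camera with an estimated correlation called 11 lists against 23. It differs from the main list test only in the correlation used, so many list calls depend on the preset value. Camera on ranks called 23 lists and fry, which does not compare a list with other genes, called 28. Arrays of the same replicate number did not deviate together (r = 0.01, 0.03, 0.10, 0.02 and -0.04), and only number 3 correlated best with its own number, so the numbers are not read as pairs. The replicate block gave 3861 higher and 3794 lower genes, and the ACTB control difference of 0.251 had an exact permutation p of 0.0625 with it, the smallest that 5 pairs allow. With housekeeping centring LYZ became -0.0454, PFKFB3 -0.006 and SFTPB -0.0125, a shift that applies to every gene. With the mean of a gene's probe sets TEK became -0.23, MYH11 0.20, SPC24 -2.17, H2BC5 0.25 and H4C8 2.36, and without shared probe sets H2AC25 became 1.16 and H4C8 6.52, because their probe sets differ in sign. Of gene values under alternatives, 4685 kept direction and side of the threshold, 132 lost the threshold, 3 gained it and 10 changed sign. Array values near background limit small signals: 372 called genes lay below the 60th percentile on all arrays. A pseudocount was not run because values were already log2.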

Other observations

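The tests of gene families, of histone probe sets, of the neighbour count without families and the fit with the ACTB covariate were chosen after the result was seen. Of 218 families of genes with a shared symbol root, 8 held more 2-fold differences in 1 direction than chance gives (limma, then a hypergeometric test). The hypergeometric test counts members as separate draws, although members of a family may vary together on the same arrays. Its p-values may therefore be too small. Centrosomal genes whose symbols begin with CEP were lower in 18 of 35 cases (adjusted p = 5.0e-07), and in 15 of 29 on specific probe sets, with CEP55, which acts in the final separation of daughter cells, lower by a log2 difference of -4.51. Pregnancy-specific glycoprotein genes were higher in 7 of 8 cases (adjusted p = 0.000106), with PSG2 (low signal in proliferating cells) at 4.31, although only 1 member had a specific probe set and it was not called as at least 2-fold higher. That p-value counts the members as separate signals, which shared probe sets cannot show. Clustered protocadherin beta genes, which encode adhesion proteins, were higher in 7 of 12 cases (adjusted p = 0.00366), with PCDHB16 (low signal in proliferating cells) at 5.24, and 7 of 11 were higher on specific probe sets. Solute carrier genes were higher in 48 and lower in 8 of 239 cases (adjusted p = 0.000169), and in 44 and 10 of 205 on specific probe sets, with the glutamate transporter gene SLC1A1 at 5.35. The medians of these 4 families, -1.15, 3.44, 1.22 and 0.26, each exceed in size the shift of -0.139 that housekeeping centring brings. The other families share more of their members with the lists in the report: NUP genes were lower in 12 of 22 cases (adjusted p = 6.8e-05), MCM genes in 8 of 11 (0.00016), KIF genes in 11 of 30 with 4 higher (0.0068) and RAD genes in 7 of 16 (0.032).

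Random grouping of the arrays was tested with 100 splits into 5 and 5. The real split gave 1323 genes lower by at least 2-fold, and the highest other split gave 0. Only 1 of 100, the real one, reached the real count. Every other split mixes the states and so puts the difference between them into the spread. The groups lie so far apart that this alone gives few calls, so the gene count restates that separation and excludes no explanation. It also says nothing of how separate cultures would vary. For lists past the threshold 3 of 100 splits reached the real 23, the highest other split also giving 23, which is under the limit of 0.05. The other splits called 0 genes and still passed between 7 and 23 of 31 lists (median 13), so camera at the preset correlation passes many lists where no gene is called, and the 2 that reached 23 exchange 1 array of each group. Such splits still carry much of the difference between the states, so no conclusion on the lists is drawn from their count.

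The 3' to 5' control difference between the groups could in principle account for the 2-fold genes, as RNA integrity or amplification differing between groups. With the ACTB control as a covariate 89.3% of them (2338 of 2617) kept direction, threshold and size limit, with a median absolute log2 difference of 1.63 before and after. This argues against a linear effect of that control as the whole cause of the 2-fold differences. Effects of RNA integrity or amplification that the control does not follow were not tested. The covariate correlates with the group (r = 0.755) and widens the errors: the ribosome biogenesis median was -0.46 before and -0.45 after (median SE 0.087 and 0.123), so lost calls there show no smaller fold. The medians of ribosomal proteins (-0.32 to -0.19, median SE 0.051 and 0.072), of replication-dependent histones (-3.03 to -2.42, 0.151 and 0.178) and of interferon-response genes (1.54 to 1.33, 0.161 and 0.194) did shrink, so that a part from RNA integrity stays open there, as does a difference in cell state, which the design names.

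Replication-dependent histone genes went apart, with 4 higher and 23 lower. With the ACTB covariate 4 of the 4 stayed at least 2-fold higher (H2BC4 at 5.58, H2AC6 at 5.18, H2BC21 at 4.39 and H2BC12 at 4.24). The control differed by only 0.25 between the groups, so the fit could hardly have removed rises of this size. No conclusion on RNA integrity or amplification as a cause of the rise is therefore drawn from it. Cross-hybridisation between near-identical histone genes stays open, since the specific probe sets on which 2 of them, H2BC4 and H2BC12, were higher are their only ones and gave the rise itself, and 0 of H2AC6 and H2BC21 had one. Specific probe sets of 20 histone genes gave 4 higher and 13 lower, the 4 being H2BC4, H2BC12, H4C8 (6.52) and H2AC25 (1.16), the last 2 of which are counted as lower from shared probe sets (-1.80 and -1.45). Polyadenylated transcripts of some histone genes in non-dividing cells may be a candidate explanation, which was not tested.

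Neighbouring genes changed the same way more often than in random order: 367 pairs both rose or both fell by at least 2-fold, against 264 on average. Chance order along the chromosomes had a permutation p of 1e-04, the smallest that 10000 orders can give. Without pairs sharing a symbol root, and with all histone genes taken as a single family, 309 pairs against 249 remained. The permutation p was again 1e-04, the smallest possible. This argues against neighbours with a shared symbol root as the whole cause. Related neighbours with unlike symbols stay in that count, so cross-hybridisation or joint regulation among them stays open. Runs of at least 4 were 8 higher genes from PSG1 to ETHE1, 6 from PCDHB7 to PCDHB14, 4 from CXXC5 to CYSTM1 and 4 from TBXAS1 to SLC37A3, and 6, 6 and 5 lower genes in histone clusters (H1-1 to H1-2, H2BC15 to H2AC17 and H1-3 to H4C8), the last of which has 4 without H4C8, whose specific probe set was higher. Of the PSG family only 1 member had a specific probe set, which was not called as at least 2-fold higher, so the run from PSG1 to ETHE1 rests mostly on shared probe sets. Regional regulation may be an explanation and was not tested beyond these counts.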
